A study of Homo sapiens with 53 samples.

How the data were processed

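Messenger RNA was measured in whole blood of people with systemic lupus erythematosus and of healthy controls. Blood was drawn into tubes that fix RNA at once, and stranded libraries were made from polyadenylated RNA and sequenced on Illumina instruments, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2 and TopHat2 2.1.1 and the genome build hg19. The program that computed the expression values, its annotation release and its use of strand are not given in the sources used here.

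The authors deposited RPKM values (reads per kilobase of transcript, divided by the mapped reads) of 54487 RefSeq transcripts in 53 libraries, and no counts. How reads were shared among the isoforms of a gene is not given in the sources used here. RPKM divides by all mapped reads, so a library in which hemoglobin transcripts took a larger share has lower RPKM for every other gene. The 10 hemoglobin genes held between 32.5% and 89.7% of the summed RPKM per library.

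Depth was estimated from the steps of low values. For 483 genes without introns, the RPKM of 1 read depends on the gene's length and the library's reads, and the number of reads was taken at which most values became whole. A depth wrong by a whole factor is not excluded. At these depths a median of 54.3% of the values per library lay within 0.1 of a whole number. At a depth fixed beforehand chance would give 20%. The depths were chosen from the same values to make them whole, so this contrast does not test them. The estimate was tested on simulated data at 3 depths, with a largest error of 0.96%. It gave 10.6 to 107 M (mega) reads in 51 libraries (median 45.0 M), 0.240 M in normal TBR replicate 1 and 0.361 M in control replicate 17. These last libraries are called the 2 shallow libraries. Of 1869 genes above 5 RPKM in all other libraries, 137 were at 0 in the first and 4 in the second. Counts of genes are therefore also given without them, an alternative chosen after seeing the data.

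Transcript values were summed by gene symbol. Of 2313 transcripts whose symbol had been lost in the table, 2188 were named by their accession. The other 125 carried at most 0.035% of a library's RPKM and were left out. Another 197 transcripts of Y-linked genes, XIST and TSIX were left out, and 23343 genes remained. Coordinates are those of GRCh38 (GENCODE annotation) by gene symbol, not of the hg19 build used upstream, since the deposited table held none.

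Groups came from the labels: 17 controls, 9 libraries each with high and normal TBR, and 9 each with high and normal NCB. The sequencing runs named in the labels put all TBR libraries and 8 controls in run 1, and all NCB libraries and 9 controls in runs 2 and 3. Cohort and run cannot be told apart, so groups were compared only within a cohort. Consecutive library numbers split run 1 into library blocks 1 and 2. The labels name no donors, so it is unknown whether a person gave blood in both cohorts, and whether libraries of a group are from separate people. The p-values measure the spread between libraries.

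The comparisons, gene lists, named-gene rule and most alternatives were fixed before the data were examined. The design named a count test, and for a table without counts limma on log2(RPKM + 0.5). The latter was used: limma 3.58.1 in R 4.3.3, with a mean-variance trend, 1 fit over all 53 libraries with a mean for each of 6 groups (controls split by cohort) and a term for run 3. Genes with a scaled RPKM of at least 1 in at least 8 libraries were tested (11340 genes), and calls were made at a Benjamini-Hochberg adjusted p under 0.05. Differences are on the log2(RPKM + 0.5) scale, which understates changes of low genes, and errors of differences are SE from limma. The values were scaled by TMM factors (trimmed mean of log ratios, trimming 30% of ratios and 5% of levels, without weights), with code written for these values. The fixed design did not say how RPKM should be scaled; the list of alternatives named TMM as the main choice. That reading was settled after the counts of calls under both scalings had been seen, so the counts of calls as deposited, and which leading genes then passed, are given beside the main ones. Scaling as deposited shifted the median log2 difference of all genes in lupus against control of the NCB cohort to -0.32, against 0.02 with TMM. In high against normal TBR the median was 0.12 with TMM and -0.10 as deposited.

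There were 18 gene lists: neutrophil granule and immature neutrophil genes, mature neutrophil, type I interferon response, interferon gamma response, plasmablast, B cell, T cell, cytotoxic T and NK cell, monocyte and dendritic cell, platelet, red cell, eosinophil and basophil, inflammatory cytokine and inflammasome, cholesterol metabolism, immediate early, cell division, ribosomal protein and respiratory chain genes. They were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with limma's fry. In random splits of the same libraries camera called a median of 8 or 9 lists, so a camera call alone is given here as a value. A score per library, the mean log2 value of a list's members, was compared between groups by an exact permutation test, two-sided, with the adjustment over the 18 lists of a comparison (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). In the NCB cohort the labels were permuted across runs 2 and 3 with no term for run, so these p-values do not allow for run. The score tests of that cohort were repeated with labels permuted within runs. Differences between cohorts were tested with 100000 resamples. Plots were made with matplotlib 3.10.9.

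Named genes follow a rule: in each of 4 comparisons, the 10 higher and 10 lower genes with the smallest adjusted p among those past the threshold, the 3 with the smallest p where a direction had none, and the 3 members of each list with the smallest p. Genes of common deletions and of the HLA, immunoglobulin and T cell receptor loci are given as group values only.

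The gene test was tested on simulated data, with independent normal errors, 11340 genes and 100 genes changed per fold size. Of the 2-fold changes it recovered 74% in high against normal TBR, 71% in high against normal NCB, 68% in lupus against control of the TBR cohort and 89% in that of the NCB cohort. Of the 4-fold changes it recovered 98%, 98%, 99% and 99%. It made 7, 10, 14 and 10 false calls. In random splits of the real libraries the highest counts of calls were 65, 3045, 3 and 2464 in the same comparisons. The simulation held no errors shared between genes, so its recovery and false calls do not carry over to the real libraries. The percentages were not compared by a test, so 68% and 89% do not explain why the cohorts differ in their counts of calls.

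Replicate numbers in the labels follow library order within each group and name no donor. Correlations of same-numbered libraries after removing group means were above 0.1 in 5 of 9 pairs of high and normal TBR, 4 of 8 of control and normal TBR, 2 of 9 of high and normal NCB, and 8 of 8 of control and high TBR (lowest 0.106, median 0.172, against a median of -0.042 for differently numbered libraries). By the rule set for this check the last pair of groups counts as paired by number. However, 3 of its 8 controls correlated best with the high TBR library of their own number. Of its differently numbered pairs 26.6% were above 0.1 as well. All its same-numbered libraries share a library block, so the number was not told apart from the block, and no pairing of donors is shown. A fit with the number as a block was run as an alternative. No libraries were duplicates: the highest correlation between libraries was 0.980.

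Alternatives were other scalings (as deposited, upper quartile, median of ratios, hemoglobin genes left out), pseudocounts of 0.1 and 1, no filter or an RPKM of 2 in 9 libraries, each cohort on its own, no run term, library blocks, no run 3, sample quality weights, a hemoglobin covariate, the replicate block and an adjusted p of 0.1. List tests and scores had further alternatives. The planned count tests could not be run on RPKM values.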

Results

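Whole blood transcriptomes of people with systemic lupus erythematosus, an autoimmune disease, were compared with those of healthy controls and between patients with different vascular disease. Low density granulocytes, neutrophil-lineage cells whose transcripts include many granule protein genes, are the study's subject. Patients were divided by 1 of 2 imaging measures. The target-to-background ratio (TBR) of radioactive glucose uptake in the vessel wall measures vascular inflammation, and the noncalcified plaque burden (NCB) measures plaque in the coronary arteries. The TBR cohort comprised 9 libraries with high TBR, 9 with normal TBR and 8 controls. The NCB cohort comprised 9 libraries with high NCB, 9 with normal NCB and 9 controls. Estimated depth was 10.6 to 107 M (mega) reads in 51 libraries, and 0.240 and 0.361 M in the 2 shallow libraries (normal TBR replicate 1 and control replicate 17). At those depths 64.7% and 49.7% of transcripts were at 0, so low genes were not detectable there.

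Hemoglobin genes took much of the RNA in every library. Their share of the summed RPKM was 69.6% ± 10.1 (SD, n = 8) in TBR cohort controls, 64.3% ± 15 (SD, n = 9) in normal TBR and 72.2% ± 11.6 (SD, n = 9) in high TBR. In the NCB cohort it was 71.0% ± 11.6 (SD, n = 9) in controls, 71.5% ± 16 (SD, n = 9) in normal NCB and 78.0% ± 8.46 (SD, n = 9) in high NCB.

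**Figure D1:**
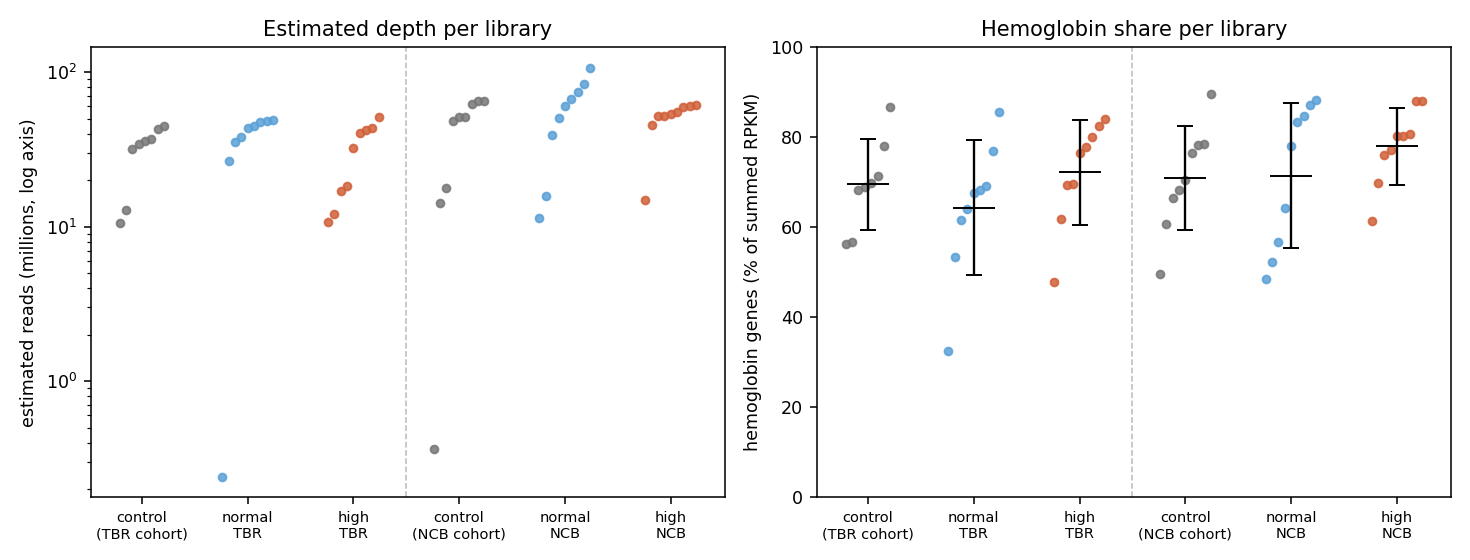
Estimated M reads per library (left, log axis) and the hemoglobin share of the summed RPKM in percent (right), 1 point per library in 6 groups, with bars for mean and SD on the right. The 2 shallow libraries lie at 0.240 and 0.361 M reads, and hemoglobin shares run from 32.5% to 89.7%.

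The first comparison asked which transcripts differed between lupus and healthy blood. In the TBR cohort, type I interferon response genes rose in lupus. All 40 measured members had positive differences, with a median log2 difference of 1.68, and their mean log2 level was 4.67 ± 0.92 (SD, n = 18) in lupus libraries against 3.07 ± 0.44 (SD, n = 8) in controls. The difference in score was 1.59 (exact permutation test, adjusted p = 0.00359), and 17 of 18 lupus libraries lay above the control mean. The members with the smallest p were USP18, which removes the ubiquitin-like protein ISG15 from its targets, XAF1, a promoter of apoptosis, and IFIT3, which helps to block viral RNA. USP18 differed by 2.40 ± 0.51 (SE), from a scaled RPKM of 1.04 ± 0.37 (SD, n = 8) in controls to 10.7 ± 6.93 (SD, n = 9) in normal TBR and 10.1 ± 6.83 (SD, n = 9) in high TBR. XAF1 differed by 1.65 ± 0.34 and IFIT3 by 1.71 ± 0.37. These 3 genes, with an adjusted p of 0.0648 in limma, did not pass over all genes, while 38 interferon genes passed when adjusted over the list alone.

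Of 11340 genes, limma called 0 in this comparison. The count at an unadjusted p under 0.05 was 559, with 567 expected by chance, and limma with sample quality weights called 847. Limma also called 0 without the 2 shallow libraries, with 675 at an unadjusted p under 0.05. The lower genes with the smallest p were AOC2 at -0.95 ± 0.23 (SE), TBC1D14 at -0.72 ± 0.18 and the readthrough transcript KLRC4-KLRK1 at -1.17 ± 0.30, which shares reads with its neighbours and is uncertain. Their adjusted p values were 0.102, 0.107 and 0.113 in limma. Camera called 10 of 18 lists, and the interferon list alone held with an estimated correlation (adjusted p = 0.00140 with an estimated correlation). Neutrophil granule genes had a median of 0.53 with 27 of 31 members positive, and mature neutrophil genes a median of -0.29 with 20 of 24 negative. Medians were -0.38 for cytotoxic cell, -0.36 for B cell, 0.32 for cell division, 0.22 for plasmablast, 0.19 for interferon gamma, 0.16 for red cell and 0.15 for platelet genes. All 9 of these lists had an adjusted p = 0.748 with an estimated correlation. Within library block 1 the interferon score difference was 1.8 (11 against 5 libraries, exact permutation p = 0.000458), and within block 2 it was 1.27 (7 against 3, exact permutation p = 0.133).

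In the NCB cohort, interferon response genes rose in lupus as well, and genes of cytotoxic T and NK cells fell by score. The cytotoxic list itself did not pass (adjusted p = 0.0511 with an estimated correlation), and its score difference was 0.27 within run 3. All 40 interferon genes had positive differences (median 1.76), 31 passed over all genes and 40 when adjusted over the list alone. IFIT3 rose by 2.16 ± 0.36 (SE; adjusted p = 0.00206 in limma), from a scaled RPKM of 28.4 ± 13.5 (SD, n = 9) in controls to 120 ± 73.7 (SD, n = 9) in normal NCB and 230 ± 159 (SD, n = 9) in high NCB. Among cytotoxic cell genes 23 of 24 were negative (median -0.81), 4 fell over all genes and 13 when adjusted over the list alone. KLRF1, an activating receptor of NK cells, fell by 1.61 ± 0.36, from 10.1 ± 4.47 scaled RPKM in controls to 4.66 ± 2.66 in normal NCB and 1.99 ± 1.3 in high NCB (SD, n = 9 each).

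The limma test called 139 genes higher and 22 lower in lupus of the NCB cohort, 161 of 11340 tested. Of the 10 leading higher genes, 7 were interferon response genes: IFIT3, PLSCR1 (1.76 ± 0.32, SE), MX2 (1.27 ± 0.24), IFI6 (2.40 ± 0.46), OASL (1.93 ± 0.38), HERC5 (1.95 ± 0.39) and OAS1 (2.04 ± 0.41). The others were IL1RN, the secreted antagonist of the interleukin-1 receptor, at 1.61 ± 0.28 (adjusted p = 0.00348 in limma), CD14, the lipopolysaccharide co-receptor of monocytes, at 1.32 ± 0.26 (adjusted p = 0.00877 in limma) and SIGLEC14 at 2.41 ± 0.48. SIGLEC14 has near-identical relatives and is absent from many genomes, so its value is uncertain. Of the 10 leading lower genes, 5 are known from NK or cytotoxic T cells: PTGDR, a prostaglandin D2 receptor (-1.23 ± 0.25), CD160 (-1.34 ± 0.28), the adaptor SH2D1B (-1.55 ± 0.32), KLRF1 and IL2RB, a chain of the receptors for interleukins 2 and 15 (-1.19 ± 0.28). The others were GSAP (-0.75 ± 0.17), YPEL1 (-0.59 ± 0.13), the pseudogene SIGLEC17P (-1.04 ± 0.23), ZNF600 (-1.19 ± 0.26) and TSPOAP1 (-0.78 ± 0.18), with the pseudogene uncertain for shared reads.

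On GRCh38 the gene IFIT3 spans chromosome 10 from 89327894 to 89340971, IL1RN chromosome 2 from 113107214 to 113134016 and CD14 chromosome 5 from 140631728 to 140633701. KLRF1 spans chromosome 12 from 9827481 to 9845007 and PTGDR chromosome 14 from 52267713 to 52276724. All are annotated as protein-coding, and the values are sums of the RPKM of their transcripts.

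**Figure D2:**
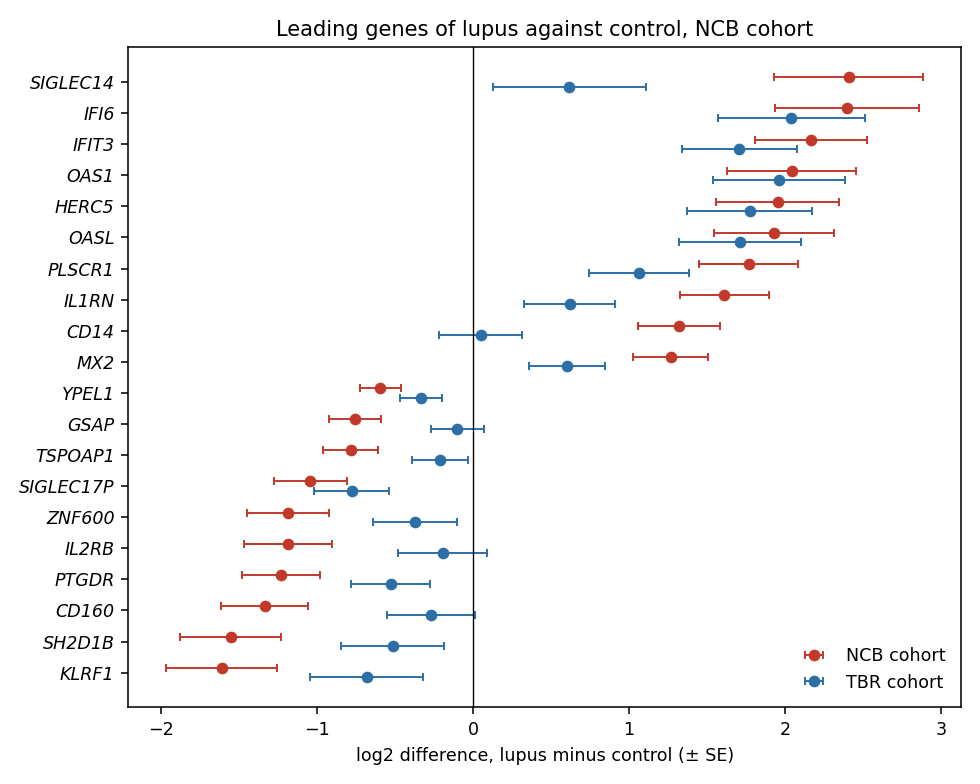
Log2 difference between lupus and control with its SE for the 10 higher and 10 lower leading genes of the NCB cohort, in red for that cohort and in blue for the TBR cohort. The 161 calls belong to the NCB cohort, and 0 genes passed in the TBR cohort.

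Scores gave the same direction for these lists in the NCB cohort. The interferon score rose from 2.76 ± 0.38 (SD, n = 9) to 4.61 ± 1.19 (SD, n = 18), a difference of 1.86 (exact permutation test, adjusted p = 0.00208), with 17 of 18 lupus libraries above the control mean. The interferon gamma score rose by 0.83 (adjusted p = 0.00208, 17 of 18, exact permutation test), and the inflammasome and cytokine score rose by 0.58 (adjusted p = 0.00386, 17 of 18, exact permutation test). Both lost their calls with RPKM as deposited, at 0.47 (adjusted p = 0.219) and 0.23 (adjusted p = 0.468, exact permutation tests). The cytotoxic score fell by 0.77 (adjusted p = 0.00914, exact permutation test), and 1 of 18 lupus libraries lay above the control mean. Granule genes had a score difference of 1.19 with 16 of 18 libraries above the control mean (adjusted p = 0.0533, exact permutation test). Mature neutrophil genes had 0.76 with 15 of 18 (adjusted p = 0.0533, exact permutation test). Both passed the exact permutation test without the 2 shallow libraries, granule genes at 1.28 (adjusted p = 0.0462) and mature neutrophil genes at 0.85 (adjusted p = 0.0331). With RPKM as deposited neither did, at 0.87 (adjusted p = 0.0909) and 0.36 (adjusted p = 0.336, exact permutation tests). The difference was 1.07 for red cell genes with 13 of 18 (adjusted p = 0.0599, exact permutation test).

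Within run 2 (15 against 6 libraries) the interferon difference was 2.06 (exact permutation p = 0.000258), the cytotoxic difference -1.12 (p = 5.53e-05) and the granule difference 1.55 (p = 0.0154). Within run 3 (3 against 3 libraries, where an exact permutation test cannot go below p = 0.10) the interferon difference was 0.78, the cytotoxic difference 0.27 and the granule difference 0.12, so the cytotoxic direction did not hold there. Interferon gamma genes differed by 1.0 in run 2 and 0.06 in run 3, inflammasome and cytokine genes by 0.75 and -0.05, and mature neutrophil genes by 1.07 and -0.13, so the inflammasome and mature neutrophil directions did not hold in run 3 either. The same was so of B cell (-0.78 and 0.83), T cell (-0.62 and 0.47), platelet (0.87 and -0.36), immediate early (0.43 and -0.11), monocyte (0.30 and -0.05) and ribosomal protein genes (-0.59 and 1.0). Of the 3 controls in run 3, 1 was the shallow replicate 17. The lupus libraries of run 3 were 1 high and 2 normal NCB, against 8 and 7 in run 2. The signs in run 3 are therefore uncertain.

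By list, camera called 15 of 18 in the NCB cohort, fry called 8, and the interferon list held with an estimated correlation (adjusted p = 0.0352 with an estimated correlation). The interferon list lost that call without the 2 shallow libraries (adjusted p = 0.0696 with an estimated correlation). Cytotoxic genes lost their call (adjusted p = 0.0511 with an estimated correlation), as did interferon gamma genes (median 0.64, 3 genes higher over all genes and 13 adjusted over the list alone) and inflammasome and cytokine genes (median 0.58, 1 higher and 13 adjusted over the list alone). Those last lists both had an adjusted p = 0.111 with an estimated correlation. Fry, which does not compare a list with other genes, called these 3 lists (adjusted p = 0.00589 each) and interferon (3.64e-04), granule (0.0442), mature neutrophil and immediate early (both 0.0306) and red cell genes (0.0486). All 31 granule genes were positive (median 1.18), 0 passed over all genes in limma and 15 passed adjusted over the list alone. The member with the smallest p was CD177, a neutrophil surface glycoprotein, at 2.12 ± 0.60 (SE, adjusted p = 0.0580 in limma). Mature neutrophil genes had a median of 0.71 with 11 passing adjusted over the list alone, red cell genes 1.06 with 6, and T cell genes -0.34 with 0. Granule, mature neutrophil, red cell, T cell and immediate early genes (median 0.42, 6 adjusted over the list alone) each had an adjusted p = 0.230 with an estimated correlation. Monocyte genes had a median of 0.39, 2 passing over all genes and 4 adjusted over the list alone (adjusted p = 0.435 with an estimated correlation). Platelet (0.56), eosinophil and basophil (-0.34) genes had an adjusted p = 0.367 with an estimated correlation. B cell genes had a median of -0.36 (adjusted p = 0.448 with an estimated correlation), cell division genes 0.39 (adjusted p = 0.431 with an estimated correlation) and ribosomal protein genes -0.18 (adjusted p = 0.626 with an estimated correlation). Plasmablast (0.06), cholesterol (0.00) and respiratory chain genes (0.21) were not called by camera.

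The scaling decided the balance of these calls. With RPKM as deposited 2 genes were higher and 12 lower, so 14.3% of calls were higher against 86.3% with TMM factors. IFIT3 then stood at 1.75 (adjusted p = 0.0717 in limma), IL1RN at 1.2 (adjusted p = 0.0717), CD14 at 0.90 (adjusted p = 0.191) and KLRF1 at -1.95 (adjusted p = 0.0114). Of the leading higher genes IFI6 alone then passed (adjusted p = 0.0485 in limma). PLSCR1 and HERC5 (both 0.172), MX2 (0.85, adjusted p = 0.273), OASL (0.152), OAS1 (0.158) and SIGLEC14 (0.0550) did not pass. Of the leading lower genes GSAP and YPEL1 (both 0.0905) and IL2RB (0.0669) did not pass, while PTGDR, CD160, SH2D1B, KLRF1, SIGLEC17P, ZNF600 and TSPOAP1 did. With sample quality weights limma called 1615 genes. Without the 2 shallow libraries 236 genes were higher and 81 lower, 317 in all, of which 159 were among the 161.

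**Figure D3:**
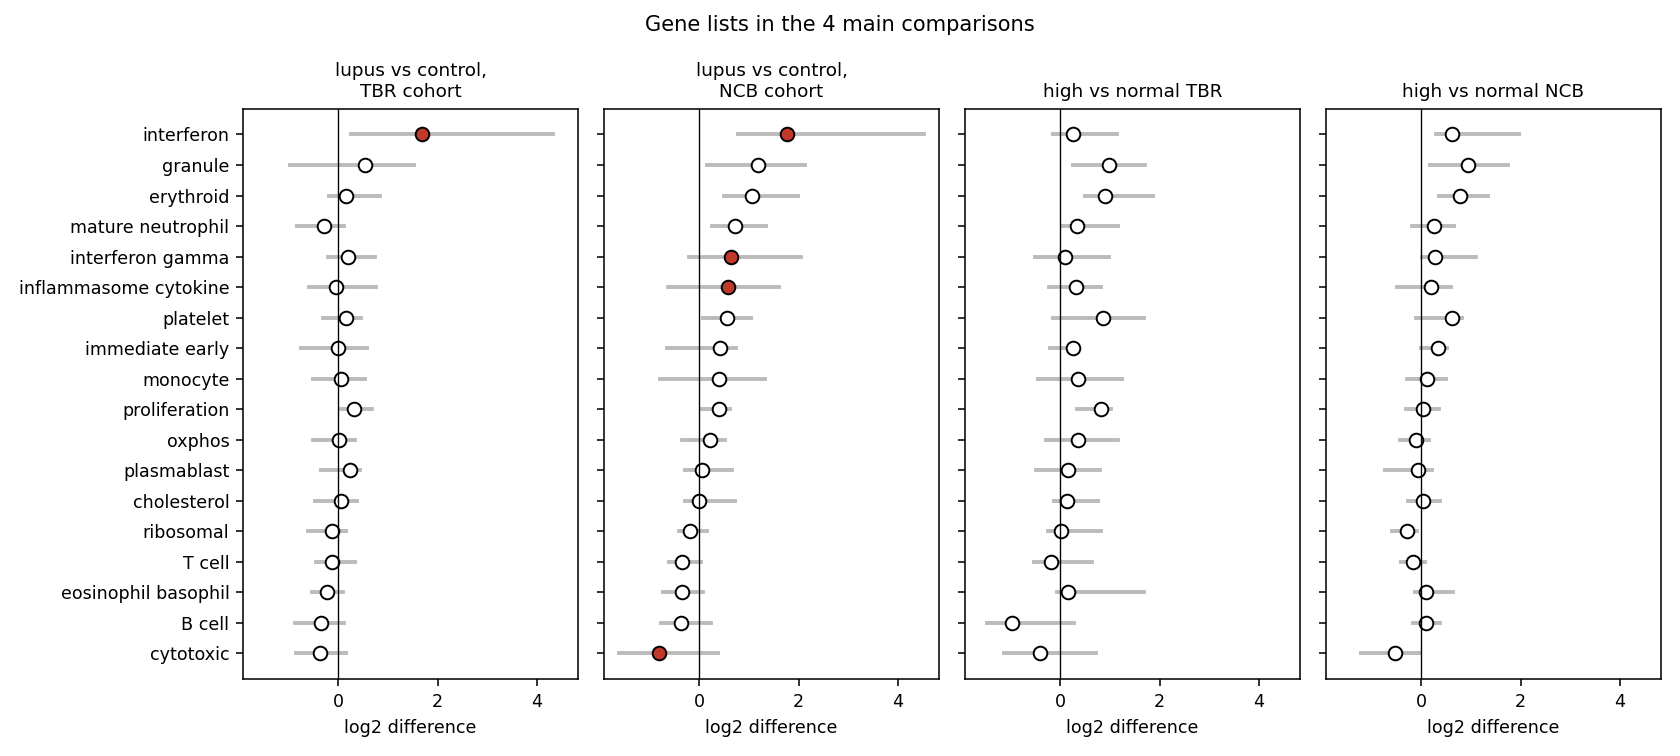
Median log2 difference of the members of 18 gene lists (circles) and the range of their members (grey lines) in 4 comparisons. Filled circles mark lists whose score passed the exact permutation test after adjustment, 1 in the TBR cohort and 4 in the NCB cohort, all in lupus against control.

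The genes called in the NCB cohort were also followed in the TBR cohort. Of the 139 higher genes 126 had a positive difference there and 65 an unadjusted p under 0.05, with medians of 1.02 in the NCB cohort and 0.44 in the TBR cohort. Among all genes 38.6% had a positive difference in the TBR cohort. Of the 22 lower genes 19 were negative there (medians -1.0 and -0.24), 4 with an unadjusted p under 0.05, while 61.4% of all genes were negative. The test of the difference between cohorts called 0 genes in limma, with 671 at an unadjusted p under 0.05 and 1188 called with sample quality weights. It also called 0 without the 2 shallow libraries, with 867 at an unadjusted p under 0.05. For the interferon score, the cohorts' difference had p = 0.620 in a permutation test. Mature neutrophil genes gave -0.30 in the TBR cohort and 0.76 in the NCB cohort (permutation p = 0.00530, adjusted p = 0.0954), which did not pass. Averaged over both cohorts, 139 genes were higher and 23 lower in lupus by limma, 85.8% higher, against 32 and 9, 78.0% higher, as deposited. Without the 2 shallow libraries there were 228 and 61.

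High and normal TBR libraries were compared to ask what goes with inflammation of the vessel wall. B cell genes were lower and neutrophil granule, cell division, red cell and platelet genes higher in high TBR, but none of their scores passed after adjustment over the 18 lists. Of 19 B cell genes 18 were negative, with a median of -0.98, and 7 passed adjusted over the list alone. PAX5, the transcription factor that holds B cell identity, differed by -1.39 ± 0.35 (SE), from 3.43 ± 2.48 (SD, n = 9) scaled RPKM in normal TBR to 0.78 ± 0.62 (SD, n = 9) in high TBR. The gene lies on chromosome 9 of GRCh38 from 36833275 to 37034185. BLNK, the B cell linker, differed by -1.05 ± 0.33 and the B cell surface protein CD72 by -1.23 ± 0.40. All 31 granule genes were positive (median 0.99), led by HP, haptoglobin, at 1.70 ± 0.63, RNASE2 at 1.37 ± 0.55 and TCN1, a vitamin B12 binding protein of granules, at 1.15 ± 0.47.

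The limma test called 0 of 11340 genes in this comparison, with 785 at an unadjusted p under 0.05 and a smallest adjusted p of 0.192, while limma with sample quality weights called 604. Chance gives 567 at that level, and without the 2 shallow libraries there were 475, with 0 called and a smallest adjusted p of 0.586. The lower genes with the smallest p were ICOSLG, the ligand of a T cell costimulator (-1.04 ± 0.23, SE), MICAL3 (-0.85 ± 0.19) and PAX5. The higher ones were C7orf73 (0.83 ± 0.22), the cell division gene UBE2C (1.0 ± 0.27) and SERPINB2 (0.82 ± 0.22). The B cell score was 1.70 ± 0.74 (SD, n = 9) in high TBR and 2.63 ± 1.23 (SD, n = 9) in normal TBR, a difference of -0.94 (exact permutation p = 0.0695, adjusted p = 0.256), with 1 of 9 high TBR libraries above the normal TBR mean. The granule score was 2.80 ± 1.35 against 1.72 ± 0.95 (SD, n = 9 each), a difference of 1.07 with 8 of 9 libraries above the mean of normal TBR (exact permutation p = 0.0712, adjusted p = 0.256). All 10 cell division genes were positive (median 0.81), 9 passed adjusted over the list alone, and their score differed by 0.79 (exact permutation p = 0.0215, adjusted p = 0.256). In the shallow normal TBR replicate 1 this score was -1.0, the value of genes at 0 RPKM. Without the 2 shallow libraries the difference was 0.64 (exact permutation p = 0.0452, adjusted p = 0.4065). Red cell genes had a median of 0.89 with 23 of 23 positive, beside the higher hemoglobin share in high TBR, and platelet genes 0.86 with 18 of 19. The platelet score differed by 0.79 with 7 of 9 libraries above the mean of normal TBR (exact permutation p = 0.0497, adjusted p = 0.256).

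Camera called 10 lists here and 0 held with an estimated correlation or with fry. The adjusted p = 0.154 with an estimated correlation for B cell genes, and it was 0.502 for granule and for platelet genes, 0.169 for cell division, 0.578 for red cell and 0.480 for cytotoxic genes (median -0.42). T cell (-0.18) and inflammasome (0.31) genes had an adjusted p = 0.592 with an estimated correlation, mature neutrophil genes (0.34) an adjusted p = 0.593 with an estimated correlation and respiratory chain genes (0.37) an adjusted p = 0.746 with an estimated correlation. Within library block 1 (5 against 6 libraries) the B cell difference was -0.86 and the granule difference 1.09, and within block 2 (4 against 3) they were -1.01 and 0.83. The cell division difference was 1.23 in block 1 and 0.15 in block 2, the red cell difference 1.35 and 0.30, and the platelet difference 1.26 and -0.02, so the platelet difference did not hold in block 2. Without the 2 shallow libraries 17 B cell genes passed adjusted over the list alone and 4 cell division genes. Interferon genes had a median of 0.25 where all genes had 0.12.

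High and normal NCB libraries were compared to ask what goes with coronary plaque. Granule and interferon genes were higher and cytotoxic cell genes lower in high NCB, and again none of their scores passed after adjustment over the 18 lists. All 31 granule genes were positive (median 0.95), led by the proteases and enzymes of primary granules PRTN3 (1.52 ± 0.60, SE) and MPO (1.14 ± 0.47) and by TCN1 (1.10 ± 0.47). PRTN3 stood at 10.4 ± 15 (SD, n = 9) scaled RPKM in high NCB and 0.97 ± 0.89 (SD, n = 9) in normal NCB. All 24 cytotoxic genes were negative (median -0.53), led by KLRC3 (-0.98 ± 0.35), which has near-identical relatives and is uncertain, KLRF1 (-1.01 ± 0.41) and the granzyme GZMH (-1.21 ± 0.53). All 40 interferon genes were positive (median 0.63), led by OAS3 (1.31 ± 0.58), OAS1 (1.03 ± 0.47) and IFIT3 (0.88 ± 0.41). With sample quality weights the interferon median was 0.0011.

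In this comparison limma called 0 genes, with 303 at an unadjusted p under 0.05 and a smallest adjusted p of 1, and 0 with sample quality weights as well. It called 0 as well without the 2 shallow libraries, with 526 at an unadjusted p under 0.05 and a smallest adjusted p of 0.709. The genes with the smallest p were the antisense transcript HM13-AS1 (0.92 ± 0.29, SE), DNASE1L1 (0.51 ± 0.16) and ITLN1 (1.04 ± 0.34), and on the lower side LOC100506159 (-1.20 ± 0.35), the pseudogene SMG1P2 (-0.95 ± 0.28) and TTC16 (-0.71 ± 0.24). The antisense transcript and the pseudogene are uncertain. The cytotoxic score was 3.28 ± 0.46 in high NCB and 3.84 ± 0.43 in normal NCB (SD, n = 9 each), a difference of -0.56, with 0 of 9 high NCB libraries above the normal NCB mean (exact permutation p = 0.0165, adjusted p = 0.173). Granule scores differed by 0.91 with 6 of 9 libraries above the mean of normal NCB (exact permutation p = 0.140, adjusted p = 0.436), and interferon scores by 0.76 with 7 of 9 (exact permutation p = 0.183, adjusted p = 0.471). Immediate early genes differed by 0.32 in score with 7 of 9 (exact permutation p = 0.0192, adjusted p = 0.173).

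Camera called 11 lists in high against normal NCB and 0 held with an estimated correlation or with fry. Cytotoxic and immediate early genes (median 0.34) had an adjusted p = 0.0900 with an estimated correlation, and granule, interferon and platelet genes (0.63) an adjusted p = 0.252 with an estimated correlation. Red cell genes (0.79) had an adjusted p = 0.267 with an estimated correlation, interferon gamma genes (0.28) an adjusted p = 0.421 with an estimated correlation, and inflammasome (0.19) and ribosomal protein genes (-0.29) an adjusted p = 0.586 with an estimated correlation. Mature neutrophil (0.27) and T cell genes (-0.16) had an adjusted p = 0.591 with an estimated correlation. Within run 2 (8 against 7 libraries) the granule difference was 1.16, the interferon difference 0.31 and the cytotoxic difference -0.49 (exact permutation p = 0.109, 0.587 and 0.0416). Run 3 held 1 high NCB library, replicate 9, and 2 normal NCB libraries, too few for a test. There the granule difference was -0.84, opposite to run 2, the interferon difference 2.35 and the cytotoxic difference -0.53. Without run 3 the median of the interferon list in high against normal NCB was 0.23.

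**Figure D4:**
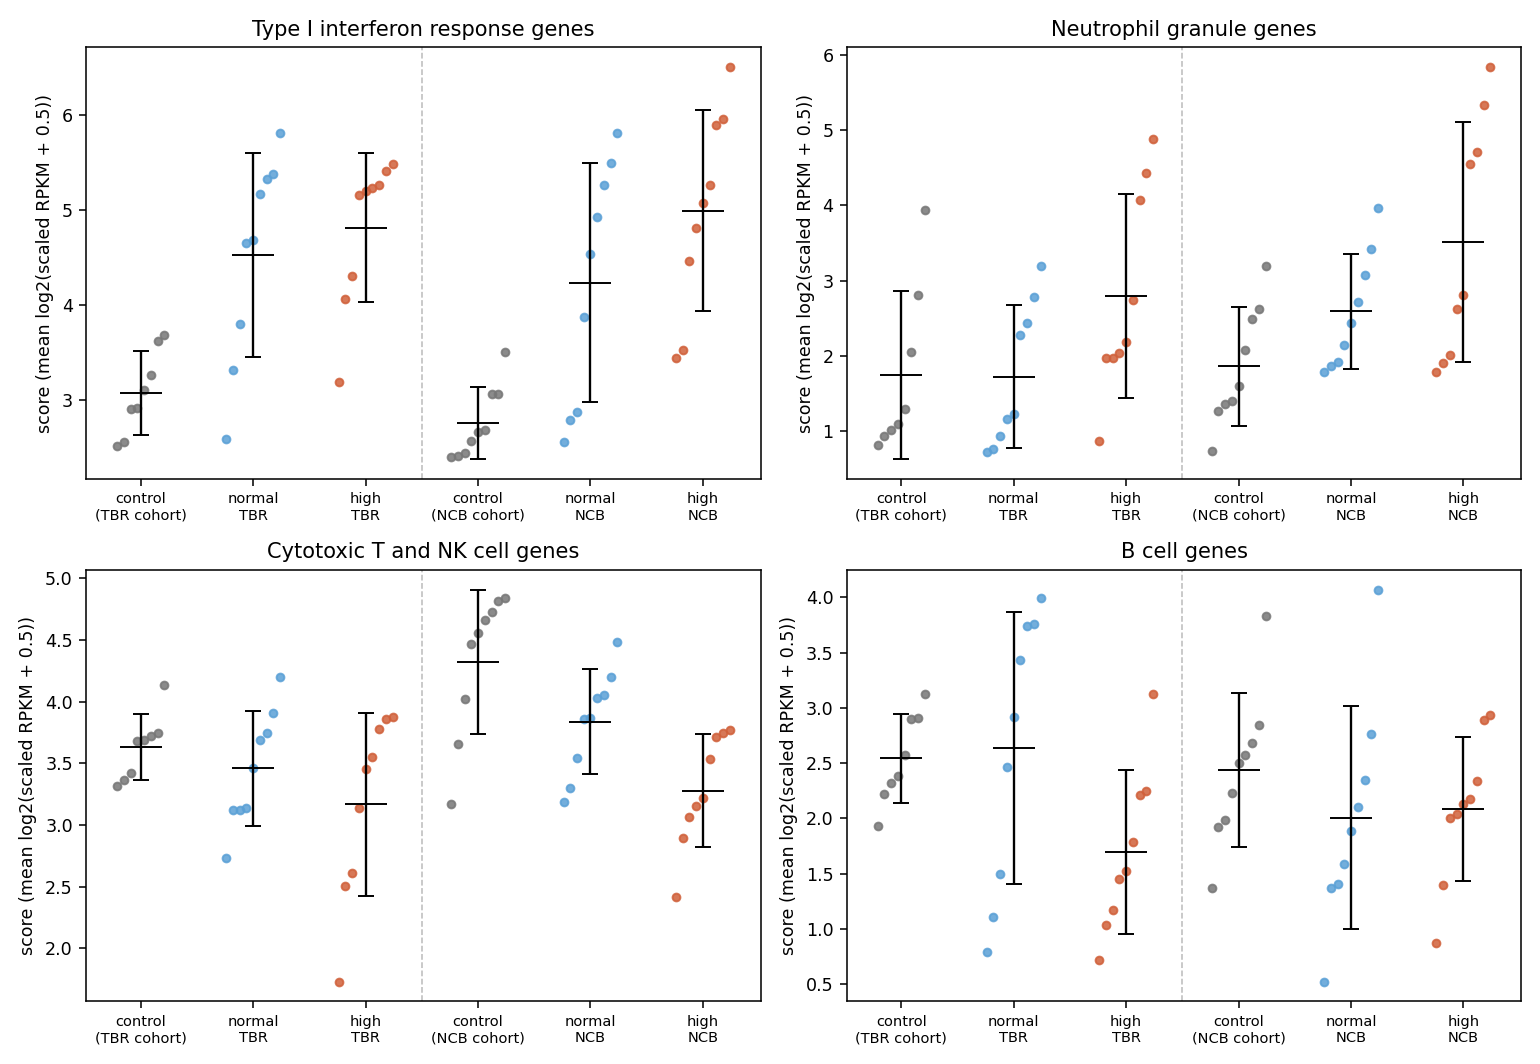
Mean log2 level of interferon, granule, cytotoxic and B cell genes per library (points) in 6 groups, with bars for mean and SD. Interferon scores of lupus groups lie above those of controls in both cohorts, at 4.67 ± 0.92 against 3.07 ± 0.44 and 4.61 ± 1.19 against 2.76 ± 0.38.

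Each patient group was also set against the controls of its cohort. High NCB against control gave 197 higher and 33 lower genes by limma, 85.7% higher, against 3 and 21, 12.5% higher, as deposited. Without the 2 shallow libraries there were 352 and 146. In high NCB 32 interferon genes passed over all genes (median 2.06, adjusted p = 0.0232 with an estimated correlation), and cytotoxic genes had a median of -1.10, with 6 lower over all genes and 18 adjusted over the list alone (adjusted p = 0.0232 with an estimated correlation). Both lists lost this call without the 2 shallow libraries (adjusted p = 0.0561 with an estimated correlation). Granule genes had a median of 1.74, with 2 passing over all genes and 25 adjusted over the list alone (adjusted p = 0.152 with an estimated correlation). In normal NCB against control limma called 0 genes (709 at an unadjusted p under 0.05, 254 called with sample quality weights), with an interferon median of 1.36 and 36 genes adjusted over the list alone (adjusted p = 0.0692 with an estimated correlation). High TBR against control gave 0 genes by limma (527 at an unadjusted p under 0.05, and 527 called with sample quality weights) and an interferon median of 1.74 (adjusted p = 0.00396 with an estimated correlation). Normal TBR against control gave 0 by limma (778 at an unadjusted p under 0.05, 1091 called with sample quality weights). There too 1 list held with an estimated correlation. The interferon score was 4.52 ± 1.07 (SD, n = 9) in normal TBR against 3.07 ± 0.44 (SD, n = 8) in controls. Averaged over both cohorts, high against normal gave 0 genes by limma (805 at an unadjusted p under 0.05, 125 called with sample quality weights), and the difference between cohorts 0 (219 at an unadjusted p under 0.05). In these 5 comparisons limma called 0 genes without the 2 shallow libraries too, and the counts at an unadjusted p under 0.05 were 1058 for normal NCB, 812 for high TBR and 465 for normal TBR against control, where chance gives 567. They were 810 for high against normal over both cohorts and 246 for the difference between cohorts.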

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

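All tests in this part were chosen after the results they address had been seen, except those of the depth and of the neutrophil and T cell mix in the NCB cohort, the fit of each cohort on its own and the test of the difference between cohorts.

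A library was singled out where its gap to the next library, divided by the range of its group, passed Dixon's 95% critical value. This was so in 12 of 132 tests over 22 quantities, where chance gives about 6.60, and 7 of the 12 fell on the 2 shallow libraries. In normal TBR, replicate 1 was lowest in estimated reads (gap over range 0.541), in genes at 1 RPKM or more (0.626) and in the monocyte (0.535), cholesterol (0.817) and cell division (0.561) scores, and highest in transcripts at 0 (0.891). Among NCB cohort controls, replicate 17 was highest in transcripts at 0 (0.778). Of the other libraries, control replicate 7 was highest in the ribosomal protein (0.572) and respiratory chain (0.688) scores among TBR cohort controls. In high TBR, replicate 8 was highest in the interferon gamma score (0.498) and replicate 3 in the monocyte score (0.532). In high NCB, replicate 9 was lowest in estimated reads (0.650); it is that group's only library of run 3.

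B cell genes were lower and granule genes higher in high than in normal TBR. The shallow library in normal TBR had a B cell score of 1.11, below its group's mean of 2.63, so it made the B cell difference smaller. Without the 2 shallow libraries that difference was -1.13 against -0.94 with them. The granule difference was 0.95 against 1.07, which argues against that library as its main cause. With RPKM as deposited the differences were -1.14 and 0.87, which argues against the scaling. Chance stays open: of 100 splits of the same libraries, 36 called at least the 10 lists of the real split, and the highest of the others called 15. A biological difference going with vascular inflammation may be present but was not shown.

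In lupus against control, 161 genes passed in the NCB cohort and 0 in the TBR cohort by limma (1632 and 559 at an unadjusted p under 0.05). The shallow library was argued against as the cause of the 0, since the smallest adjusted p was 0.0651 without the 2 shallow libraries. The spread shared with the NCB cohort may have a part, since 24 genes passed in the TBR cohort fitted on its own. With the hemoglobin share as a covariate 151 genes passed, and 0 of the named genes lost a call. This argues against the hemoglobin share as the source of the named genes' calls. Whether the rest of the 151 are among the 161 was not compared, so for the other calls it stays open. Whether lupus acts differently in the cohorts stays open, with 0 genes in the limma test of that difference (671 at an unadjusted p under 0.05), and cohort and run are confounded.

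For the 161 genes, 4 of 100 splits called as many, the real one included, although the highest of the others called 2464. That share is under the 0.05 set for this check. It was also under 0.05 for the 15 lists of that comparison (2 of 100, highest other 15). The 162 genes averaged over both cohorts gave the same share (2 of 100, highest other 996). The share was above 0.05 for the 230 genes of high NCB against control (8 of 100, highest other 2445). So it was for the 11 lists of high against normal NCB (31 of 100, highest other 14). The 10 lists of lupus against control in the TBR cohort were above it too (33 of 100, highest other 13). These shares were not adjusted over the comparisons, and labels were shuffled across runs 2 and 3. Only values with TMM factors were split, so chance is not excluded for any of these counts. Where limma called 0 genes all 100 splits called as many, which a count of 0 fixes, so this tests nothing. The highest other was then 65 in high against normal TBR, 3045 in high against normal NCB, 3 in lupus against control of the TBR cohort, 2410 in high against normal over both cohorts and 581 in normal NCB against control. It was 1 in high TBR and 0 in normal TBR against control, and 84 and 355 in the differences between cohorts in high against normal and in lupus against control.

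Splits that call many times the real count point to a structure of the NCB cohort that its groups do not explain. The first principal component of the residuals of its 26 deeper libraries held 43% of the variance, and 3 relations were tested with it. The component went with the hemoglobin share at r = 0.574 (permutation p = 0.00207, adjusted p = 0.00621, rho 0.566, p = 0.00288; r = 0.5 without the 2 farthest libraries) and with estimated reads at r = -0.395 (permutation p = 0.0420, adjusted p = 0.0476, rho -0.494, p = 0.0112; r = -0.459 without them). The score of mature neutrophil minus T cell genes gave r = 0.391 (permutation p = 0.0476, adjusted p = 0.0476, rho 0.282, p = 0.162), but r = 0.158 without the 2 farthest libraries, so this relation rests on them. The component was computed from data that include the genes of this score, and its sign was set to make this r positive. The score is thus no outside measure of the cell mix. Hemoglobin share, depth and cell mix could each be a source, and within run 2 (21 libraries) their r was 0.563, -0.358 and 0.434.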

How the results depend on the processing

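Chosen only after seeing the data were the tests with RPKM as deposited, median of ratios factors, a pseudocount of 1, a stricter filter of 2 RPKM in 9 libraries and a hemoglobin covariate, those without the 2 shallow libraries, C1q genes without high TBR replicate 3, and the scores as deposited or without these.

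Of 205 counts of genes under alternatives, 160 stayed at 0 or within 1.5 times the first count, 39 were higher and 6 lower. Most comparisons had a first count of 0, which cannot fall, so this tally does not show stable counts. In lupus against control of the NCB cohort the count ran from 14 to 1615. Of 4230 values of named genes 4012 stayed on their side of the threshold, 197 passed newly and 21 no longer passed. Of 1566 list tests these numbers were 1362, 44 and 152, and 8 reversed. Of 324 score tests they were 309, 13 and 2. Among these were 36 score tests of the NCB cohort with labels permuted within runs. Of those, 33 kept their side and 3 passed newly. Most named genes and scores had not passed at first and so could not lose a call, so these tallies do not show stable calls either. Of the lost calls, 16 of the 21 for genes and the 2 for scores came with RPKM as deposited. A change of direction between values that did not pass was not counted as a reversal. The interferon score of lupus against control passed under every score alternative in both cohorts, with the highest adjusted p at 0.0178 in the TBR and 0.0426 in the NCB cohort, both as deposited. High against normal NCB gave 0 genes by limma in all 18 alternatives (at an unadjusted p under 0.05, 303 in the first fit and 526 without the 2 shallow libraries). For the changes below the cause was not tested unless stated.

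With RPKM as deposited, 14 genes passed in lupus against control of the NCB cohort, 41 over both cohorts and 24 in high NCB against control. The interferon list in high against normal TBR then had a median of -0.0087, where all genes had -0.10, and was called by camera as higher than other genes (adjusted p = 0.0489). With no filter 93 and 113 genes passed in lupus of the NCB cohort and in high NCB against control, where more genes were tested. With each cohort fitted on its own 24 genes passed in lupus of the TBR cohort and 133 in high NCB against control.

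With the library block in place of the run, 7 genes passed in lupus of the TBR cohort, 287 in that of the NCB cohort, 245 over both, 2 in high TBR against control and 378 in high NCB against control. Without run 3 there were 518 in lupus of the NCB cohort, 261 over both cohorts, 1017 in high NCB and 39 in normal NCB against control, and the interferon list in high against normal NCB fell short (median 0.23, adjusted p = 0.0898). At an adjusted p of 0.1, by construction a wider threshold, 19, 272 and 261 genes passed in lupus of the TBR cohort, of the NCB cohort and over both, and 457 in high NCB against control.

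Sample quality weights changed the counts most. They gave 604 genes in high against normal TBR, 847 and 1615 in lupus of the TBR and NCB cohorts, 1273 over both, 125 in high against normal over both, and 1188 in the difference between cohorts in lupus. Against control they gave 527 in high TBR, 1091 in normal TBR, 1675 in high NCB and 254 in normal NCB. In 4 list tests camera's direction, which is relative to the other genes, turned: the median was 0.37 for plasmablast genes in high against normal TBR, 0.0011 for interferon and -0.21 for cell division genes in high against normal NCB, and -0.091 for platelet genes in lupus of the TBR cohort. The lowest weights were 0.033 in normal TBR replicate 1 and 0.163 in control replicate 17. Counts under weights were not tested on other splits of the libraries.

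Without the 2 shallow libraries and with weights, the same counts were 587, 815, 1614, 1249, 48 and 1194, then 484, 1073, 1667 and 249 against control. The medians were 0.37, -0.0019, -0.21 and -0.091. Without these libraries and without weights 317 genes passed in lupus of the NCB cohort, 289 over both cohorts and 498 in high NCB against control. With the hemoglobin share as a covariate, 11 genes passed in lupus of the TBR cohort and 4 in high TBR against control, and the interferon list in high against normal TBR was called (median 0.43, adjusted p = 0.00292).

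With an estimated correlation in camera, which cannot change a median, the granule list lost its calls. Its medians were 0.99 in high against normal TBR (adjusted p = 0.502) and 0.95 in that of NCB (adjusted p = 0.252). In lupus they were 0.53 in the TBR cohort (adjusted p = 0.748) and 1.18 in the NCB cohort (adjusted p = 0.230). The interferon list in high against normal NCB, with a median of 0.63, lost its call as well (adjusted p = 0.252). Fry in 1 direction gave 0.165, 0.390, 0.870 and, for interferon, 0.390, and of these passed only granule genes in lupus of the NCB cohort (0.0442). Fry in either direction gave 0.937, 0.998, 0.966 and 0.172 for granule and 0.998 for interferon genes.

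The replicate block gave 0 genes by limma in the 5 comparisons it was fitted to, high against normal in each cohort and the TBR cohort against control, and it changed no other call of genes. Of 54 list tests with it 51 kept their side, 2 passed newly and 1 no longer. For patients against controls of the NCB cohort, no paired analysis was possible because these groups share only 1 number.

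The planned count tests were not run, since the deposited values are RPKM. Depth limits low genes most in the 2 shallow libraries, where 64.7% and 49.7% of transcripts were at 0.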

Other observations

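Tests of the granule score against other scores were chosen only after the scores had been seen, as were the comparison of the cohorts across genes and the fits of C1q genes without libraries.

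Complement C1q genes, which monocytes and macrophages express, had higher means in high TBR, which rest in part on 1 library. C1QA stood at 3.98 ± 6.37 (SD, n = 9) scaled RPKM in high TBR and 1.16 ± 1.33 (SD, n = 9) in normal TBR, C1QB at 3.87 ± 5.71 against 0.86 ± 0.76 and C1QC at 1.72 ± 2.19 against 0.34 ± 0.32. On the log2 scale the differences were 1.03 ± 0.46, 1.24 ± 0.43 and 1.04 ± 0.33 (SE), with an adjusted p of 0.657 in limma for each, so none passed. Leaving out high TBR replicate 3, whose monocyte score lay apart from its group, gave 0.66 ± 0.43, 0.89 ± 0.40 and 0.76 ± 0.31 (SE, adjusted p = 0.662, 0.661 and 0.661 in limma). Leaving out the 2 shallow libraries as well gave 0.49 ± 0.42, 0.74 ± 0.40 and 0.67 ± 0.31. The 3 genes lie side by side on chromosome 1 of GRCh38, C1QA from 22636506, C1QC from 22643630 and C1QB from 22652762. ITLN1, a lectin also known as omentin, and SERPINB2, an inhibitor of plasminogen activators, were among the 3 higher genes with the smallest p in high NCB (1.04 ± 0.34) and high TBR (0.82 ± 0.22), without passing.

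Most of the genes called in lupus of the NCB cohort lay outside the lists. The lists hold only a small part of the tested genes, so this does not mean that calls were rarer on them. Of 139 higher genes 37 were on a list, 31 of them interferon genes, and 102 were not; of 22 lower genes 18 were on none. Among the higher members of other lists were SERPING1, the inhibitor of the first complement component, at 2.05 ± 0.48 (SE, adjusted p = 0.0169 in limma), ETV7, a transcription factor, at 1.68 ± 0.43 (adjusted p = 0.0316) and CD300E, a monocyte receptor, at 0.76 ± 0.20 (adjusted p = 0.0362). With RPKM as deposited none of these 3 passed, at 1.65 (adjusted p = 0.221), 1.28 (adjusted p = 0.269) and 0.36 (adjusted p = 0.423 in limma).

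Across 11340 genes, which are not independent replicates, the lupus differences of the cohorts correlated at r = 0.427 (rho 0.296). Of 100 groupings of the NCB cohort libraries, the real one included, 5 gave an r as high, and the others ran from -0.533 to 0.556. The differences of high against normal correlated at r = 0.258 (rho 0.179), and 20 of 100 were as high.

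A hypothesis was that granule genes, as markers of low density granulocytes, go with the interferon response in lupus. Over 35 deeper lupus libraries, on deviations from the group means, r was -0.24 (permutation p = 0.166, adjusted p = 0.199 over 6 relations). Spearman's rho was -0.255 (permutation p = 0.139), and r was -0.177 without the 2 farthest libraries. No positive relation within groups was seen, but these values do not exclude a weak one, and differences between groups were not covered. Within cohorts r was -0.122 (TBR) and -0.334 (NCB). Another was that they go with mature neutrophil genes: r was 0.635 (permutation p = 4.0e-05, adjusted p = 0.00024; rho 0.555, p = 0.00057; 0.574 without the 2 farthest libraries), 0.694 in the TBR and 0.583 in the NCB cohort. This is consistent with a shared neutrophil abundance, found and tested on the same data, and r was 0.434 with RPKM as deposited. Of the other 4 relations, T cell scores gave -0.517 (adjusted p = 0.00411; -0.404 without the 2 farthest, -0.316 as deposited), platelet 0.389 (adjusted p = 0.0430; 0.063 as deposited), red cell 0.359 (adjusted p = 0.0516; 0.049 as deposited) and B cell scores -0.116 (adjusted p = 0.505; -0.421 in the TBR and 0.225 in the NCB cohort).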
